A study of Mus musculus with 5 samples.

How the data were processed

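The assay for transposase-accessible chromatin with sequencing (ATAC-seq), which marks open chromatin by where a transposase inserts adapters, was run on nuclei of C17.2 cells, an established mouse multipotent neural stem cell line. Per the labels' protocols, the cells grew in a serum-containing medium and differentiation was induced by a change to a serum-free medium with N2 supplement. There were 5 libraries, taken at 0, 0.5, 1, 1.5 and 2 h after induction, with 1 library per time. The series' design text names only the baseline, 1 h and 2 h, with 1 replicate per group, and the labels give all 5 times.

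Bowtie2, MACS2, deepTools and the mouse build GRCm38 (mm10) are named per the submitters' processing notes, which give no versions, settings or order of steps. How reads were shifted for the transposase, how duplicates were treated and which peak threshold was used are not given in the sources used here. The deposited table lists 34714 short sites called transcription start sites, 1 to 23 bp wide with a median of 5 bp, each with a position, and 33952 of them with a gene symbol and Ensembl identifier. Where the list of sites came from is not given in the sources used here. Per the file headers, each library's column is named after a BED file, and its values are whole numbers from 0 to 10. The values were read here as the number of entries of that library's BED file over the site, with 0 meaning that no entry covered it. This reading is an inference from the values. Pairs of neighbouring sites at most 200 bp apart, with 2 or more entries at either site, were pooled over the 5 libraries. Of 56261 such pairs, 93.6% held equal values. In 98.6% of the 3621 pairs that differed, 1 of the sites held 0. Stacked entries of a shared interval, such as a peak listed once per summit, give such steps, and separate reads would not. The values are therefore neither read counts nor normalised signal. The read depth behind each library is unknown, so the precision of a single value is unknown, and a site at 0 was not called covered in that library, which does not show closed chromatin.

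The gene name of a site is the table's own annotation. Of the named sites, 27776 overlapped their gene, and 51.2% of named sites had the same strand as their gene, so strand was not used. The symbol Galnt2l was attached to 394 sites over 4131 kb of chromosome 8, from 120101194 to 124231799, far more than a single gene, and it was kept as 1 gene and never named as a result. A gene table of assembly GRCm38.p6, the same build, matched 7549 of 8034 symbols. Of the sites with a matched symbol, 98.2% lay within 5000 bp of that gene. Sites lay a median of 324 bp downstream of the annotated 5′ end of their gene, 11.8% within 50 bp and 74.2% within 1000 bp. Exons, introns and UTRs were not annotated here. Coordinates are those of the deposited table.

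Each gene was given 1 value per library, that of its site with the highest mean over the 5 libraries. A gene was called covered in a library where that site held 1 or more entries, gained where it was uncovered at 0 h and covered at the later time, and lost in the reverse case. Log2 ratios were computed on log2(entries + 1), a scale that understates the difference of low genes. Numbers of genes past a 2-fold difference, in either direction, were taken among the 4056 genes whose mean over the 5 libraries was at or above the median gene (2.2 entries). As 4 of these libraries are later than 0 h, this filter, fixed before the data were examined, favours gained over lost genes, and genes such as Gapdh could not rank among the lowest. The planned design allowed for counts, normalised signal or peak sets, and with the unit found, no library-size scaling and no Poisson interval was used. With 1 library per time there is no replicate error: no test between times was run, and no p-value, SD or SE is given. Wilson 95% intervals on shares of genes cover counting error over genes only.

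For 32 gene lists fixed before the data were examined, the median log2 ratio at each time was set against 10000 random lists of the same size matched on the mean over the 5 libraries in 20 bins. A list with 5 or more measured genes was said to stand apart where its median lay at or below percentile 0.5 or at or above percentile 99.5, limits meant to take 1 in 100 pairs of a list and a time by chance. Medians of small whole numbers are often tied at 0, so this share is nominal. The rule describes these libraries and is not a p-value. On simulated unchanged data (each gene's 5 values shuffled, 8034 genes, lists of 20), the rule called 2.0% of 200 lists with no member altered, 61.0% with 8 members doubled and 100% with all members doubled. With means in place of medians these shares were 1.5%, 81.0% and 100%. The simulated lists were drawn only from genes with a mean at or above the median gene, and were set against fewer random lists. These shares therefore do not carry over to lists with many members at 0 or with fewer members. The count of genes past 2-fold recovered 200 of 200 genes seeded with a 2-fold difference among 4056 genes of an otherwise identical library, which checks the arithmetic only and says nothing of variation between libraries.

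The rule for named genes, also fixed before the data were examined, took for each time the 8 genes with the highest and the 8 with the lowest log2 ratio against 0 h among the 4056 genes, leaving out unnamed gene models, and 18 fixed genes whatever their values. Ties were ordered by the higher mean and then by the alphabet, an order set after the values were seen. Of the fixed genes 12 were measured, and Sox2, Neurod1, Tubb3, Dcx, Gfap and Pnpt1 were not analysed here. Some of the measured fixed genes are not reported here. Any other gene named as an example of a list was chosen after its values were seen. Agreement between times was the correlation across genes of log2 ratios, set beside 100 shuffles of each gene's 5 values. Alternatives covered the pseudocount (10 in place of 1), quantile normalisation, the filter, the mean over a gene's sites, the fold threshold (1.5), the matching of lists and the baseline. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.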

Results

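Chromatin accessibility was profiled by ATAC-seq in C17.2 mouse neural progenitor cells at 0, 0.5, 1, 1.5 and 2 h after induction of neural differentiation, with 1 library per time. The table gave, for each of 34714 short sites annotated as transcription start sites, a whole number from 0 to 10 per library, read here as the number of entries of that library's BED file over the site. The sites carried 8034 gene symbols. Read depth was unknown, and all differences between times are differences between single libraries, with no replicate check and no test.

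The site of the immediate early gene Egr1 held 4 entries in each of the 5 libraries, and that of Tfam, the mitochondrial transcription and packaging factor, held 2 in each. Hes1, a Notch effector that maintains progenitors, held 1 entry in each library at a site upstream of the gene. Pax6, a neural progenitor transcription factor, held 0 in each at a site 7456 bp inside the gene. At 0 h, 5847 of 8034 genes were covered (72.8%, Wilson 95% interval 71.8 to 73.7%). The covered share was 76.6% at 0.5 h (75.6 to 77.5%), 72.4% at 1 h (71.4 to 73.4%), 79.3% at 1.5 h (78.4 to 80.2%) and 78.3% at 2 h (77.4 to 79.2%). The shares of 0 h and 1 h were close, and those of 0.5, 1.5 and 2 h were higher. The same genes were scored in every library and the spread between libraries is unknown, so these intervals do not compare the times. Counted by site, 47.6% of sites were covered at 0 h, 58.7% at 0.5 h, 51.2% at 1 h, 66.9% at 1.5 h and 65.7% at 2 h. When sites within 500 bp of one another were merged into 9219 regions, a count chosen after seeing the data, the shares were 66.0%, 69.2%, 65.3%, 71.8% and 70.8%. The total number of entries over all sites was 42527 at 0 h, 56773 at 0.5 h, 45254 at 1 h, 65824 at 1.5 h and 59437 at 2 h. Covered sites held a mean of 2.58, 2.79, 2.55, 2.83 and 2.61 entries at these times. Of the 8034 genes, 5544 were covered in all 5 libraries and 1542 in none.

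**Figure D1:**
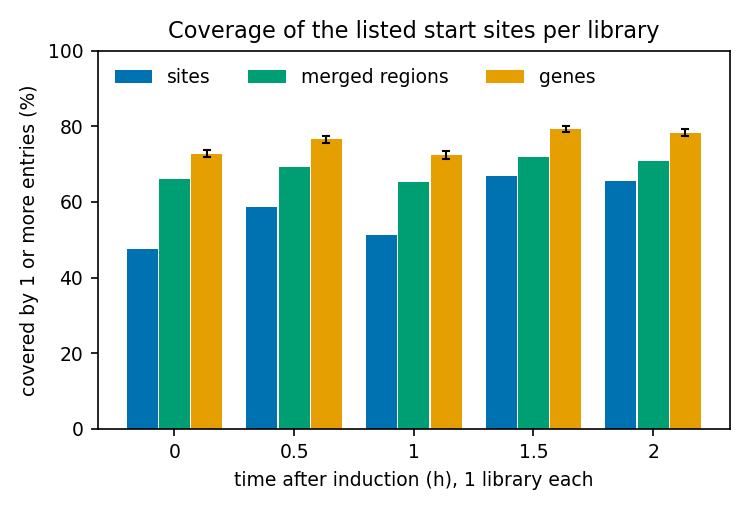
Bars give the percent of sites, of regions merged from sites within 500 bp and of genes covered by 1 or more entries in each library, against time after induction in hours. Error bars on the gene bars are Wilson 95% intervals over genes. The share of sites was 47.6% at 0 h and 66.9% at 1.5 h, and the share of genes was 72.8% and 79.3%.

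Coverage was highest just upstream of annotated 5′ ends in every library, and the 1.5 h and 0 h libraries differed most 500 to 750 bp downstream of them. Among 2761 sites within 100 bp upstream of the 5′ end, 70.0% were covered at 0 h and 80.6% at 1.5 h. Among 2784 sites 500 to 750 bp downstream of it, 36.1% were covered at 0 h, 52.5% at 0.5 h, 41.7% at 1 h, 63.0% at 1.5 h and 59.7% at 2 h.

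**Figure D2:**
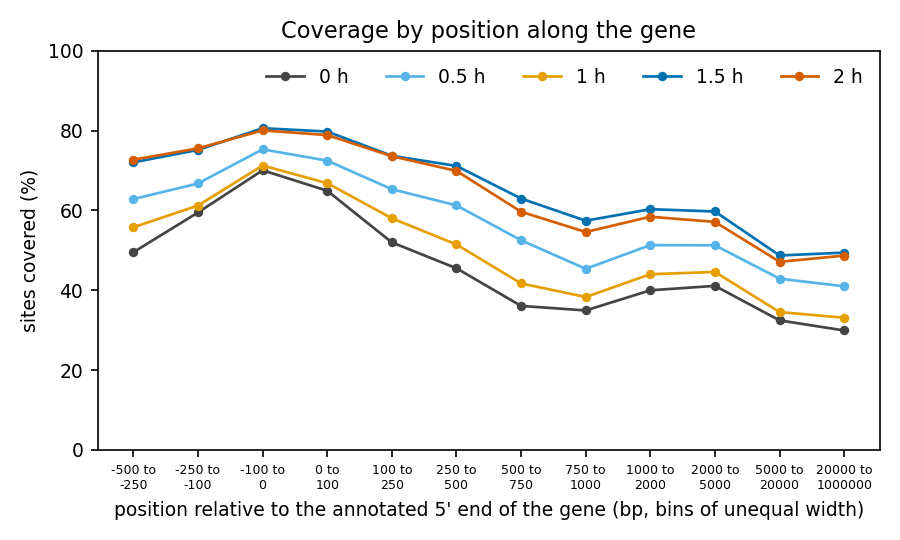
Lines give the percent of sites covered in each of the 5 libraries, by position of the site relative to the annotated 5′ end of its gene in bp, in bins of unequal width. At 500 to 750 bp downstream the 1.5 h library covered 63.0% of sites and the 0 h library 36.1%.

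The comparison of 0.5 h with 0 h asks what differed earliest after induction. Jun, a subunit of the AP-1 transcription factor, had 0 entries at 0 h and 6 at 0.5 h over a site 674 bp inside the gene (chromosome 4, 95051546 to 95051551, GRCm38), then 0 at 1 h, 5 at 1.5 h and 0 at 2 h. Trak1, an adaptor that links mitochondria to kinesin motors, had 0 entries at 0 h and 6 at 0.5 h at its 5′ end (chromosome 9, 121297492 to 121297493). Rsf1, a histone chaperone of a chromatin remodelling complex, and the methyltransferase gene Mettl9 also had 0 and 6 entries, and the cytokine receptor gene Crlf2 had 0 and 7. Atp5j, a subunit of mitochondrial ATP synthase, and Gabpa, an ETS factor of genes for mitochondrial proteins, each had 0 entries at 0 h and 5 at 0.5 h. Their sites lie 149 bp apart on chromosome 16 (84835605 to 84835608 and 84835754 to 84835756) and share their values in all libraries, so they count as a single region. The mitotic kinase gene Nek6 had 0 and 5 entries, at a site 27966 bp inside the gene.

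Genes with lower values at 0.5 h were fewer. Nsd1, a histone H3 lysine methyltransferase, had 5 entries at 0 h and 0 at 0.5 h, and the nuclear import receptor gene Tnpo2 had 8 and 1 (chromosome 8, 85038129 to 85038137, 1260 bp inside the gene). The chaperone gene Hsp90aa1, the Fanconi anaemia core gene Faap100, the heterochromatin protein gene Cbx1, the nucleolar gene Gnl3 and the chromatin remodeller gene Pbrm1 each had 5 and 1, and Pltp, a phospholipid transfer protein, had 3 and 0. The sites of Gnl3 and Pbrm1 lie 152 bp apart with equal values. Among the 4056 genes with a mean at or above the median, 311 were at least 2-fold higher and 59 at least 2-fold lower, on the log2(entries + 1) scale. Of the 311, 107 had 0 entries at 0 h, and of the 59, 2 had 0 entries at 0.5 h. The filter on the mean over 5 libraries, of which 4 are later than 0 h, removes genes covered mainly at 0 h, so it kept 107 of 386 gained genes and 2 of 81 lost ones. With no filter, 657 were higher and 176 lower. Among all genes, 386 of the 2187 uncovered at 0 h were covered at 0.5 h (17.6%, Wilson 95% interval 16.1 to 19.3%), and 81 of the 5847 covered at 0 h were uncovered (1.39%, 1.12 to 1.72%).

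Of 25 measured proneural and neuronal transcription factor genes, 7 had more entries at 0.5 h than at 0 h, 0 had fewer and 18 had equal numbers, and the number covered was 5 at 0 h and 9 at 0.5 h. Neurog1, a proneural factor, had 0 entries at 0 h and 2 at 0.5 h, the early B-cell factor gene Ebf1 had 0 and 2, and Neurog2 had 2 and 4. The median of the list was fixed at 0 by members at 0 in all libraries, and its mean of 0.31 lay at percentile 99.9 of random lists. The mean was not the preset measure. By it 2 of 104 pairs of a list and a time passed the limits, where 1.04 are expected by chance. Of 16 genes of G1/S and DNA replication, 10 had more entries and 0 fewer, among them E2f1 with 2 and 4 and Ccne2 with 4 and 7, and the median of 0.37 lay at percentile 97.505. Of 15 genes of respiratory complexes II to V, 8 had more and 3 fewer (median 0.42, percentile 96.9), with Atp5j at 0 and 5 entries and Cyc1, a cytochrome c1 gene, at 6 and 2. At 2 h the order of this list was turned, with 4 more and 6 fewer. Of 27 immediate early genes, 7 had more entries at 0.5 h, 5 fewer and 15 equal numbers, and the median was 0 (percentile 48.5). At 1 h and 2 h, 3 of the 27 had more, and 7 and 9 had fewer. Fos had 4 entries at 0 h and 3 at 0.5 h, and Myc had 3 and 2. By the preset rule on medians, no list stood apart at 0.5 h.

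The comparison of 1 h with 0 h showed fewer genes with higher values, and more with lower ones, than that of 0.5 h. Dab2ip, a Ras GTPase-activating protein, had 0 entries at 0 h and 6 at 1 h (chromosome 2, 35661420 to 35661427, 102978 bp inside the gene). Nek6 had 0 and 5. Atp8b2, a lipid flippase, Rev3l, the catalytic subunit of DNA polymerase zeta, Atp5j, Gabpa, Agbl5, a tubulin deglutamylase, and Wwc2 each had 0 and 4. Lower at 1 h were Tnpo2 with 8 and 0, the adhesion receptor gene Adgrl3 (chromosome 5, 81020751 to 81020757) with 7 and 0, the lysine methyltransferase gene Setd7 with 7 and 0, and the kinesin gene Kifc3 with 7 and 0 at a site 60305 bp inside the gene. Cobll1, Baz2a, a silencer of ribosomal DNA, Ltbp1, which holds latent TGF-beta, and the kinase gene Akt1 each had 5 and 0. At 1.5 h Adgrl3 held 5 entries, Setd7 6, Cobll1 6, Baz2a 6 and Akt1 4. Among the 4056 genes, 207 were at least 2-fold higher at 1 h than at 0 h and 159 at least 2-fold lower. Counting any difference the order turned, with 1191 higher and 1274 lower, as it did at 2-fold with no filter on the mean, with 379 higher and 401 lower. Of the 2187 genes uncovered at 0 h, 225 were covered at 1 h (10.3%, Wilson 95% interval 9.08 to 11.6%), and of the 5847 covered, 255 were uncovered (4.36%, 3.87 to 4.92%). This order turned too, to 583 gained and 537 lost, where 2 or more entries were required, a definition chosen after seeing the data. There were 157 genes covered in every library except that of 1 h.

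At 1 h the proneural list had 4 of 25 genes covered, against 5 at 0 h, and Neurog1 and Ebf1 held 0 entries again. At 1.5 h and at 2 h, 9 of the 25 were covered, with 8 higher and 1 lower than at 0 h, Neurog1 held 1 entry and Ebf1 2, and the mean lay at percentiles 98.9 and 98.4. Sox4, a neuronal SoxC factor, had 2 entries at 0 h and 0 at 1 h. Of 32 chromatin regulator genes, 7 had more entries at 1 h, 9 fewer and 16 equal numbers (median 0, percentile 50.2), with the H3K27 demethylase gene Kdm6a at 0 and 4 and its paralogue Kdm6b at 4 and 0. Of 14 mitochondrial protein import genes, 2 had more and 7 fewer (median −0.13, percentile 4.19), with Tomm6 at 1 and 3 entries. Of 22 mitochondrial ribosomal protein genes 6 had more and 9 fewer, and of 40 cytosolic ribosomal protein genes, matched by symbol, 14 had more and 6 fewer, each with a median of 0. The cytosolic order was turned at 2 h, with 6 more and 9 fewer. No list stood apart at 1 h.

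Of the 4 later libraries, that of 1.5 h had the most genes at least 2-fold higher than at 0 h and the most gained. Nr3c1, the glucocorticoid receptor gene, had 0 entries at 0 h and 7 at 1.5 h at a site 28829 bp inside the gene (chromosome 18, 39490589 to 39490596). The Wnt receptor gene Fzd8 (chromosome 18, 9213688 to 9213691, 834 bp inside), the TGF-beta signalling repressor gene Skil (chromosome 3, 31094645, upstream of the 5′ end), the histone demethylase gene Kdm7a, Atp8b2 and Crlf2 also had 0 and 7. Fzd8 had 0 entries at 0.5 and 1 h as well. Rev3l and Naa15, an auxiliary subunit of an N-terminal acetyltransferase, had 0 and 6. Lower at 1.5 h were the stress-response gene Gadd45b with 5 and 1, the insulin-like growth factor binding protein gene Igfbp4 with 5 and 1, and Tnpo2 with 8 and 2. Pdcd6ip and Cntnap1, a paranodal adhesion protein, had 7 and 2 each, and the palmitoyltransferase gene Zdhhc8 had 7 and 2. Slc49a4 and Zfp36l1, an mRNA decay factor, had 4 and 1 each. Of the 4056 genes, 368 were at least 2-fold higher and 62 at least 2-fold lower, and counting any difference 1556 were higher and 1126 lower. Of the genes uncovered at 0 h, 567 were covered (25.9%, Wilson 95% interval 24.1 to 27.8%), and of those covered at 0 h, 42 were uncovered (0.718%, 0.532 to 0.969%).

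Nes, which encodes the progenitor filament nestin, had 0 entries at 0, 0.5, 1 and 2 h and 2 at 1.5 h. Of 20 neural progenitor genes, 8 had more entries at 1.5 h than at 0 h, 3 fewer and 9 equal numbers (median 0, percentile 45.2), with Rest, a repressor of neuronal genes, at 2 and 6, Cdh2 at 3 and 7 and Notch2 at 4 and 2. Of 32 chromatin regulator genes, 27 were covered at 0 h and 32 at 1.5 h, and 13 had more entries and 8 fewer. At 2 h, 27 were covered, and 11 had more entries than at 0 h and 12 fewer. At 1.5 h the remodeller ATPase gene Smarca2 held 5 entries and the methyltransferase gene Kmt2d 4, against 0 each at 0 h. Of 19 FoxO and growth factor withdrawal targets, 13 had more entries and 2 fewer (median 0.32, percentile 95.4), with Rictor at 2 and 5 and Mxi1 at 2 and 4. At 2 h, 5 of the 19 had more and 4 fewer (median 0, percentile 49.8). Of 7 complex I genes, 1 had more entries at 1.5 h than at 0 h and 4 fewer (median −0.42, percentile 1.42), with Ndufv1 at 3 and 2. Of 16 Hox genes, 2 were covered at 0 h, 1 at 1.5 h and 3 at 2 h. No list stood apart at 1.5 h.

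At 2 h, the last time, Nr3c1 and Fzd8 again held 7 entries against 0 at 0 h, and Runx2, an osteoblast transcription factor, had 0 and 7 at a site 78632 bp inside the gene. Rev3l, Rsf1, the zinc finger factor gene Zic5 (chromosome 14, 122464431 to 122464432), Kdm7a and Sgms1, a sphingomyelin synthase, each had 0 and 6. Lower at 2 h were Chd4, the ATPase of the NuRD remodelling complex, with 5 and 0 (chromosome 6, 125095924 to 125095928, 54 bp upstream of the 5′ end), the histone chaperone gene Anp32a with 5 and 0, and Akt1 with 5 and 0. Jade2, the H3K4 demethylase gene Kdm5a and Tmcc2 each had 4 and 0. Svil, an actin-binding protein, had 8 and 1, as did Tnpo2, which was among the 8 lowest at every time. Of the 4056 genes, 294 were at least 2-fold higher and 152 at least 2-fold lower, but counting any difference 1246 were higher and 1414 lower. Of the genes uncovered at 0 h, 530 were covered (24.2%, Wilson 95% interval 22.5 to 26.1%), and of those covered, 83 were uncovered (1.42%, 1.15 to 1.76%).

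Gapdh, a glycolytic enzyme, had 6 entries at 0 h and 0 in each of the 4 later libraries, at a site 1448 bp inside the gene (chromosome 6, 125165018 to 125165020). Of 12 glycolysis genes, 3 had more entries at 2 h, 5 fewer and 4 equal numbers. The kinase gene Pdk1 had 4 and 2, and Pgam1 had 2 and 4. The median was 0 (percentile 48.9) and the mean of −0.34 lay at percentile 0.43. Gapdh, the lowest of the list (log2 ratio −2.81), made up most of that mean. Of 12 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 1 had more entries at 2 h and 8 fewer (median −0.42, percentile 0.945), with Dld at 5 and 2, Dlst at 3 and 1 and Sucla2 at 4 and 2. Of 14 mitochondrial protein import genes, 5 had more entries and 2 fewer at 1.5 h, and 2 had more and 8 fewer at 2 h (median −0.29, percentile 2.04). Of 14 genes of mitochondrial RNA import, decay and processing, 2 had more, 3 fewer and 9 equal numbers (median 0, percentile 49.7), with Fastkd3 at 1 and 3. Of 22 Notch pathway genes 5 had more and 5 fewer, with the Notch effector gene Hey1 at 0 and 3 and Notch1 at 0 and 3. Of 20 neuronal cytoskeleton and synapse genes, 11 were covered at both times, and 2 had more and 2 fewer entries. Of 11 sterol synthesis genes 4 had more entries and 1 fewer at 0.5 h, and 1 had more and 4 fewer at 2 h. Actb had 2 entries at 0 h and at 2 h.

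**Figure D3:**
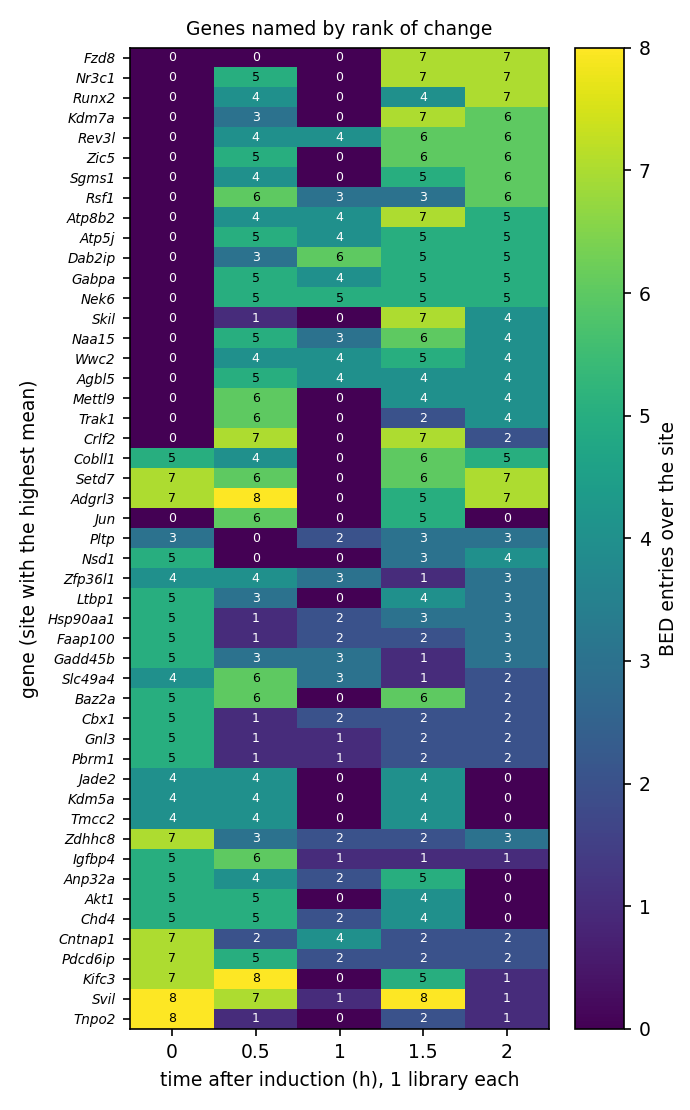
Each row is a gene named by rank of change and each column a library, by time after induction in hours, with colour and number giving the BED entries over the gene's site with the highest mean. Of the 49 genes, 21 had 0 entries at 0 h, and Adgrl3, Setd7 and Cobll1 had 0 at 1 h with 5 or more at 0 h, 1.5 h and 2 h.

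Few marker genes of other cell types were among the listed sites. The origin of the site list is unknown, so their small number says nothing of which cells were present. Of 7 astrocyte genes, 2 were covered at 0 h and 3 at 2 h, with the nuclear factor gene Nfib at 0 and 5 entries. Of 8 oligodendrocyte lineage genes, 3 were covered at 0 h and 2 at 2 h. All 3 mesenchymal genes were covered at 0 h and 2 h, as was the 1 gene of microglia and blood cells. Of 4 endothelial and epithelial genes, 1 was covered at 0 h and 1 at 2 h. The lists for microglia and blood cells (1 gene), mesenchymal cells (3), endothelial and epithelial cells (4), liver and muscle (0), olfactory and vomeronasal receptors (2) and the mitochondrial genome (0) were too small for a percentile. Over the other 26 lists and 4 times, 0 of 104 medians stood apart by the preset rule, and 97 medians were exactly 0. For 3 lists (12 of the 104 medians) this was fixed in advance, since most members held 0 entries in all 5 libraries: 16 of 25 proneural, 13 of 16 Hox and 5 of 8 oligodendrocyte lineage genes. The tricarboxylic acid list at 2 h and the G1/S list at 0.5 h had the lowest and highest percentiles. The 7 medians other than 0 came from the lists of G1/S, complexes II to V, FoxO targets, complex I, the tricarboxylic acid cycle and, at 1 h and 2 h, protein import. Each of these lists had a median of 0 at its other times.

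Overlaps between times differed by direction. Of the genes at least 2-fold higher, 257 were shared by 1.5 h and 2 h, and 145 by 1 h and 2 h. Independent lists would share 26.7 and 15, but both lists of a pair rest on the same 0 h library. Shuffling each gene's 5 values, which keeps that library shared, gave an overlap of 87.6 (66 to 111 over shuffles and pairs) from shorter lists of 155 genes on average. Of those at least 2-fold lower, 48 were shared by 1 h and 2 h, against 5.96 for independent lists and 30.1 (16 to 46) for shuffled values. The other 5 pairs of times shared 16 to 24 such genes, below the shuffled mean, with at least 1 of their lists far shorter than the 153 genes of the shuffled ones. Across the 4056 genes, the log2 ratios of pairs of times correlated with Pearson's r from 0.56 (1 h and 1.5 h) to 0.81 (1.5 h and 2 h), with a median of 0.66, where shuffled values gave 0.50 from the shared 0 h library. Spearman's rho was 0.53 and 0.73 for these pairs. The covariance exceeded the shuffled one by 0.046 (0.5 h and 1 h) to 0.16 (1.5 h and 2 h). The single 0 h library cannot be split, so part of the sharing may come from it, and genes are not independent replicates. With no library shared, r was 0.23 for the steps 0 to 0.5 h and 1 to 1.5 h, 0.11 for the steps 0.5 to 1 h and 1.5 to 2 h, and −0.027 for the steps 0 to 0.5 h and 1.5 to 2 h.

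No gene had more entries at every step from 0 to 2 h, and none had fewer at every step. Over all 120 orders of the 5 libraries, the mean was 0.208 such genes per direction and the highest 3. A count of 0 is therefore near what any order gives and does not speak against steady change. Allowing ties, 377 of the 4056 genes never had fewer entries at a later time and had more at 2 h than at 0 h, and 52 of the 120 orders of the 5 libraries gave as many. In the other direction, 562 genes never had more and had fewer at 2 h, and 2 of the 120 orders gave as many, this one included. Among the named genes, Rev3l (0, 4, 4, 6 and 6 entries), Nek6 (0 and then 5 at each time) and Fzd8 were never lower at a later time, Pdcd6ip (7, 5, 2, 2 and 2) and Gapdh never higher, and Tnpo2, Adgrl3 and Jun followed neither order.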

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

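The nestedness test, the steady-opening test and the test of loss rates by number of entries were chosen after the results they measure were seen, and the other tests were set before.

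The 762 sites with no gene name were used in no gene comparison, and they were covered well above the 0.394% that a count of 0 would allow. The covered share was 30.6% at 0 h, 33.6% at 0.5 h, 29.5% at 1 h, 35.4% at 1.5 h and 35.6% at 2 h, with Wilson 95% intervals of 27.4 to 33.9% at 0 h and 32.2 to 39.0% at 2 h. The order of the times was close to that of the named genes, with 1 h lowest. Counted over all sites, the like unit, 0 h was lowest, with 47.6% covered against 51.2% at 1 h.

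More sites were covered at 0.5, 1.5 and 2 h than at 0 h, and 0.824% of the sites covered at 0 h were uncovered at 1.5 h, nearly the nested sets that a gain in sequencing depth or peak-calling sensitivity would give. The share lost was 1.77% of sites with 1 entry, 0.973% with 2, 0.307% with 3 and 0.352% with 4 or more. The last 2 shares rest on 13 of 4237 and 12 of 3408 sites, too few to tell a fall from none. The demand for a fall at every class was tightened after the values were seen. Depth or sensitivity as the explanation stays open. A half-hour batch was predicted to give the highest correlation of changes among the 15 pairs sharing no library, and it did not. The highest, 0.351, set 0 h and 1 h against 1.5 h and 2 h. The best pair setting 0.5 h and 1.5 h against whole-hour libraries had 0.225. This argues against such a batch as the leading split only. A ranking of splits cannot exclude a half-hour batch beside an early-late difference, so that stays open. The biological explanation, an opening that grows steadily with time, would need the 1 h library to cover at least as many sites as that of 0.5 h, and it covered 2596 fewer. With 1 library per time, the spread between libraries is unknown, so this cannot be told apart from a library of lower sensitivity at 1 h.

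Gained sites lay beside intervals already present at 0 h. Of the 6847 sites gained at 1.5 h, 66.9% lay within 500 bp of a site covered at 0 h, against 19.7% of the 11355 that stayed uncovered. This excess of 47.2 percentage points argues against a closeness common to all uncovered sites. The 11355 include 10621 sites at 0 in all 5 libraries, so the excess does not tell other causes apart. The groups were not matched on how densely sites are listed, so clustering of listed sites stays open. Wider peaks at active promoters and more sensitive peak calling may each give the excess, and no biological explanation was tested for this pattern.

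Sites with many entries at 0 h and none at 1 h, such as those of Adgrl3, Setd7 and Akt1, numbered 126 of 3408 with 4 or more entries. They were lost at 0.285 times the rate of sites with 1 entry (3.70% against 13.0%), as lower sensitivity at 1 h would give, and the 1 h library covered fewer genes than that of 0 h (5817 against 5847) and fewer merged regions (6021 against 6081). It covered more sites (17769 against 16512), which goes the other way, so sensitivity cannot be told apart from other causes. Of these sites, 54.8% lay within 500 bp of a site still covered at 1 h, which leaves a shift of interval edges open for part of them. A closing of these sites at 1 h, the biological explanation the time course names, was not tested and stays open.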

How the results depend on the processing

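The restriction to sites near 5′ ends, the 2-entry definition, merged regions, any-site coverage, covered-member counts and the runs without Galnt2l or the 1 h library were chosen after seeing the data. The order of 1 h and 0 h turned between sites and merged regions or genes, between 2-fold counts and any difference, with no filter, and for gained against lost genes with 2 or more entries; at 2 h it turned between 2-fold counts and any difference. Among named genes and single lists, 862 alternative values stayed within their bounds, 75 log2 ratios of named genes moved (64 of them with pseudocount 10) and 7 list percentiles passed the rule for standing apart, and the filter does not enter a named gene's ratio. For each sentence that follows, values are in the order 0.5, 1, 1.5 and 2 h. A pseudocount of 10 left 0 genes past 2-fold in either direction at any time, as only a move between 0 and 10 entries reaches 2-fold on that scale. Quantile normalisation gave 182, 110, 211 and 171 genes higher and 59, 96, 62 and 112 lower. With no filter, 657, 379, 916 and 766 genes were higher and 176, 401, 147 and 280 lower, by construction more genes. A 1.5-fold threshold gave 641, 423, 684 and 570 higher and 211, 420, 279 and 460 lower. The mean over a gene's sites gave 451, 263, 544 and 470 genes higher. With coverage defined as 2 or more entries, 827, 583, 1042 and 902 genes were gained and 282, 537, 283 and 486 lost. Within 1000 bp of 5′ ends, 53, 180, 28 and 56 genes were lost. Merged regions were covered at 66.0% (0 h), 69.2%, 65.3%, 71.8% and 70.8%, so 1 h lay below 0 h by region and above it by site. Without the 1 h library in the choice of sites and genes, 326, 402 and 321 genes were higher at 0.5, 1.5 and 2 h. By the median, 1 of the list-time pairs stood apart under each of 3 alternatives: histone genes at 1 h with only genes at or above the median mean, complex I genes at 1.5 h with the mean over sites, and G1/S genes at 0.5 h with matching on the 0 h value. With means 2 pairs did (proneural factors at 0.5 h and glycolysis at 2 h), and 2 with the change in covered members, the same lists and times. Of 104 pairs, 1.04 are expected to pass by chance. The median correlation between times was 0.62 with pseudocount 10, 0.63 with quantile normalisation, 0.61 with no filter and 0.69 with the mean over sites. With the step before as the baseline and no library shared, the median was 0.11. Changes over single steps are not changes against 0 h, so how much of this difference comes from the shared 0 h library was not tested. Among all pairs of changes sharing no library, the highest correlation was 0.351. Quantile normalisation, which breaks ties, gave 44 genes higher and 24 lower at every step. Where no construction is named, the cause was not tested. Unknown read depth limits every count of covered sites. No paired analysis was possible because each time has 1 library and no test between times was run.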

Other observations

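The membership of the transcription factor families was corrected after their first values were seen, to leave out genes that only share a family's letters, and the count of patterns over libraries was chosen after the result was seen.

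Lists not described with the comparisons held genes with differing values in both directions at 2 h. Of 16 Wnt and TGF-beta early response genes, 5 had more entries at 2 h than at 0 h and 3 fewer (median 0, percentile 46.9), with Skil at 0 and 4 and Tgfb1, the ligand gene, at 4 and 1. Of 17 purine and nucleotide salvage genes, 3 had more and 6 fewer (percentile 49.2), with the uridine kinase gene Uck2 at 0 and 5. Of 13 integrated stress response genes, 1 had more, 2 fewer and 10 equal numbers (percentile 50.3), and Ppp1r15a, a phosphatase subunit that ends the response, had 5 entries at 0 h, 3 at 0.5 h, 3 at 1 h, 2 at 1.5 h and 1 at 2 h. Of 12 NRF2 and hypoxia targets, 5 had more and 4 fewer (percentile 48.4), with the glutathione synthesis gene Gclc at 0 and 2. Of 13 genes of G2/M and mitosis 2 had more and 2 fewer (percentile 49.0), and of 31 replication-dependent histone genes 12 had more and 9 fewer (percentile 49.9).

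Of 158 genes of 28 developmental transcription factor families (Fox, Sox, Pax, Lhx, Zic, Tbx, Hox and others), 61 were covered at 0 h and 73 at 2 h. Those gained at 2 h included Six5, with 0 entries at 0 h and 6 at 2 h, Zic5 with 0 and 6, Foxp4 with 0 and 5, Tcf7, a Wnt effector, with 0 and 4, and Foxm1, a mitotic regulator, with 0 and 3. Emx2 and Lhx2, regulators of cortical patterning, each had 0 entries at 0, 0.5 and 1 h, 2 at 1.5 h and 1 at 2 h. Sox6 and Nkx2-2 were the 2 members lost at 2 h, with 2 and 1 entries at 0 h. These examples were chosen after their values were seen.

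The hypothesis that such genes gain coverage more often than others was set against random draws of genes in the same single libraries, and was not borne out. Of the 97 members uncovered at 0 h, 14 were covered at 2 h (14.4%), against 530 of 2187 genes (24.2%). The number lay at percentile 0.375 of 10000 random draws matched on the number of sites per gene, so members were gained less often than matched genes. The percentile was 1.45 at 0.5 h, 0.285 at 1 h and 0.12 at 1.5 h, all against the same 0 h library.

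Several genes alternated between libraries rather than following time. Svil had 8, 7, 1, 8 and 1 entries at 0, 0.5, 1, 1.5 and 2 h, and Kdm5a, Jade2 and Tmcc2 each had 4, 4, 0, 4 and 0. In all, 29 genes were covered at 0, 0.5 and 1.5 h and uncovered at 1 and 2 h, and 0 genes had the opposite pattern. Jun was among 19 genes covered at 0.5 and 1.5 h alone, and 0 genes were covered at 0, 1 and 2 h alone. A further 192 genes were covered in every library except that of 0 h, and 121 at 1.5 and 2 h alone.

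The covered sites of 1.5 h and 2 h were the most alike, sharing 92.4% of the sites covered in either, and those of 0 h and 1.5 h shared 70.1%. Within the whole-hour libraries, 16512 sites were covered at 0 h, 17769 at 1 h and 22790 at 2 h, and within the half-hour libraries 20365 at 0.5 h and 23223 at 1.5 h. The X chromosome had 38.9% of 656 sites covered at 0 h and 54.7% at 2 h.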
